A study of Mus musculus with 14 samples.

How the data were processed

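Hearts of mice on the C57BL/6J background were profiled by RNA sequencing in 14 libraries, 1 per sample. Per the labels' protocols, total RNA was extracted with a column kit, messenger RNA was enriched on oligo-dT beads, and strand-specific libraries were prepared and amplified by PCR. The submitters' processing notes name bcl2fastq 2.17.1.14 (conversion of sequencer output to reads), STAR 2.4.2a (a spliced read aligner), Picard 2.10.3 and the mouse builds mm10 and GRCm38, without saying how each was used. The deposited values are whole-number counts of reads per gene, not normalised, with separate columns per the file headers for the coding and untranslated parts of each gene and for ambiguous reads. The layout of the columns is that of the QoRTs counter. Its version, the gene annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap an antisense partner are treated as uncertain. In all 14 files the gene count equalled the sum of its coding and untranslated parts.

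The tables held 51912 genes by versioned Ensembl identifier. Symbols and positions came from the GENCODE M21 annotation of GRCm38, in which 51719 identifiers were found, 47648 of them with the same version. Reads in no annotated feature and ambiguous reads were left out of library sizes and tests. They made up 15.3% ± 2.42 and 1.52% ± 0.048 (SD, n = 14) of the counted reads. Counts assigned to genes ranged from 11385818 to 20369637 per library. Genes that share sequence with close relatives or pseudogenes can lose or gain reads in such counting, and this is stated beside the genes concerned. No 2 libraries of a group agreed within sampling noise. The lowest chi-square per degree of freedom between 2 libraries of a group was 3.73, so no library was taken as a copy of another and each entered as a replicate. This does not show that each came from its own animal.

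Libraries were grouped by the genotype and surgery in the labels: 4 wild-type sham, 4 knockout sham, 2 wild-type TAC and 4 knockout TAC. Age was 11 weeks in 2 libraries of each sham group and 10 weeks in the others, so no TAC library has an 11-week partner. The labels give neither the duration of TAC nor the sex. Replicate numbers follow the order of deposit and pair nothing. The labels do not say in words that each library came from its own animal, so p-values measure the spread between these samples, which may be technical in part.

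Genes with too few counts were removed by filterByExpr (minimum count 10), leaving 15651 tested and 36261 not tested. Counts were scaled by TMM factors and tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3. The 14 libraries entered 1 fit with 1 coefficient per group, so the groups shared an estimate of the spread (biological coefficient of variation 11.8%). The comparisons were TAC against sham in each genotype, knockout against wild type in each surgery, and the difference between the TAC effects (interaction). Adjusted p-values are Benjamini-Hochberg values over the 15651 genes, with a threshold of 0.05. Levels are CPM (counts scaled to a common library size) on TMM-scaled libraries, as mean ± SD. Fold changes are edgeR estimates and are not given for genes under 0.5 CPM in the lower group, a limit chosen after values were seen. Single values were compared by exact two-sided permutation tests.

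Gene lists were written before the data were examined. They comprised 34 lists with 764 entries, of which 752 had a row in the tables. The 6 sex-linked transcripts were kept out of the set tests. Its Y-linked member Ddx3y was at 166 to 241 CPM in all 14 libraries. The other 33 lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 33 lists within each comparison. The same test with a correlation estimated from the data, and fry, a rotation test of whether a list's genes move on balance one way, were alternatives. Camera's preset correlation called 17 lists after TAC in wild type, 20 after TAC in knockout, 16 between genotypes in sham hearts, 10 between genotypes after TAC and 10 in the interaction. With an estimated correlation, 1, 0, 0, 1 and 1 of these remained called, the fibrillar matrix list in each case. Fry called 14, 13, 0, 6 and 1 lists. For each list the number of members past 0.05 over all genes and adjusted over the list alone is given.

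Named genes followed a rule fixed before the data were examined. Clk3, Nppa, Nppb, Myh7, Myh6, Acta1, Ankrd1 and Atp2a2 were followed in every comparison. In each comparison with a reference group, the 8 largest rises and 8 largest falls were taken among protein-coding or otherwise named genes past the threshold, with at least 1 CPM in the higher group and no overlap between libraries. In the interaction the genes of smallest adjusted p were taken, and the 5 of smallest p where fewer than 5 passed. Up to 4 members of smallest p were taken from each list described, and genes within 5 Mb of Clk3 past the threshold in the genotype comparisons. Which lists to describe by member was chosen after values were seen.

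Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with sample weights, no filter and a stricter filter (50 counts in 4 libraries), age as a factor, 10-week libraries alone, only the groups compared, stricter thresholds, and leaving out each library in turn. The alternatives added after seeing the data were the share of reads in no feature as a covariate, a clock gene score as a covariate, coding-sequence counts alone, and leaving out knockout sham 4 and knockout TAC 3. Sequences of 3 pseudogenes were compared with Rplp0 by blastn 2.17.0+ on GRCm38.

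The procedure was tested on simulated counts drawn from the means, fitted dispersions and library sizes of these data, over 15651 genes with 200 changed. The changed genes were taken only among those with a mean of at least 1 CPM. The shares below therefore do not cover genes of lower counts, and they assume that every group varies as fitted. Of genes changed 1.5-fold, edgeR recovered 41.8% for TAC in wild type, 62.7% for TAC in knockout, 67.2% for genotype in sham hearts, 50.7% for genotype after TAC and 14.9% for the interaction. At 2-fold the shares were 76.1%, 91%, 82.1%, 82.1% and 55.2%, and at 4-fold 97%, 98.5%, 100%, 97% and 86.4%. False calls made up 5.92%, 4%, 2.35%, 4.38% and 4.59% of all calls. A list of genes shifted by 0.5 on the log2 scale was called by camera in all 5 comparisons. Simulated genes were drawn independently of one another, so that result gives no check of the preset correlation. By the shares of genes recovered, small differences are often missed at this depth and number of libraries, above all in the interaction.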

Results

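Gene expression was measured in mouse hearts that carried the wild-type Clk3 gene or were labelled as Clk3 knockouts, after sham surgery or TAC. Clk3 is a CDC-like kinase, a family that phosphorylates the SR proteins of pre-mRNA splicing. TAC is taken as transverse aortic constriction, a standard operation that narrows the aorta and places a pressure load on the left ventricle. The series asks what Clk3 does as the heart enlarges. The 14 libraries comprised 4 wild-type sham (12836936 to 20369637 gene counts per library), 4 knockout sham (13334635 to 14733656), 2 wild-type TAC (13287464 and 13441034) and 4 knockout TAC (11385818 to 18080226). The share of reads outside annotated features was 15.8% ± 1.37 in wild-type sham, 18.0% ± 0.833 in knockout sham, 12.8% ± 2.92 in wild-type TAC and 13.3% ± 0.87 in knockout TAC (SD, n = 4, 4, 2 and 4). It was lower after TAC in all knockout libraries (exact two-sided permutation test, p = 0.0286, n = 4 and 4). In wild type the difference was −3.01 percentage points (exact permutation p = 0.133, n = 2 and 4), and wild-type TAC 2 lay within the sham range.

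Clk3 (ENSMUSG00000032316.8, chromosome 9, 57750624 to 57765860, minus strand, GRCm38) still had counts in every library labelled knockout, and gene counts do not show which exons the allele removes. In sham hearts it stood at 73.2, 92.5, 77.2 and 96.0 CPM in wild type and at 67.4, 64.8, 62.8 and 66.9 CPM in knockout (84.7 ± 11.3 against 65.5 ± 2.12, SD, n = 4 and 4). All 4 knockout values were lower, which gives the smallest p the exact two-sided permutation test allows (p = 0.0286). Over all genes the difference of −0.37 ± 0.13 (log2, SE) did not pass (edgeR adjusted p = 0.158). After TAC the levels were 54.2 and 92.3 CPM in wild type and 64.9, 54.9, 50.8 and 61.4 CPM in knockout, a difference of −0.34 ± 0.16 (adjusted p = 0.35, and p = 0.4 by exact permutation, with 0.0667 the smallest possible). The sign turned to 0.09 without wild-type TAC 2. Clk3 did not change with TAC in either genotype beyond the spread (−0.21, adjusted p = 0.457 in wild type and −0.18, adjusted p = 0.405 in knockout). The library labelled wild-type TAC 1 therefore lay within the knockout range, for the coding part of Clk3 as well (42.9 CPM, against 38.7 to 46.5 in the 8 knockout libraries). Its untranslated part, at 11.3 CPM, lay below the 12.0 to 21.1 CPM of those 8. This library also had the lowest share of reads outside annotated features of all libraries (10.7%). Whether its low Clk3 follows that share was not tested. A pseudogene of the ribosomal protein gene Rplp0, Gm8730 (ENSMUSG00000063696.7, chromosome 8, 102864845 to 102865798), was at 57.4 to 67.1 CPM in the 8 knockout libraries and 66.8 CPM in the library labelled wild-type TAC 1, against 1.26 to 1.63 CPM in the other 5 wild-type libraries. The cardiac response genes of that library followed its surgery label: Nppa was 1912 CPM, against 1808 in wild-type TAC 2. Every value for wild-type TAC below rests in part on this library.

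**Figure D1:**
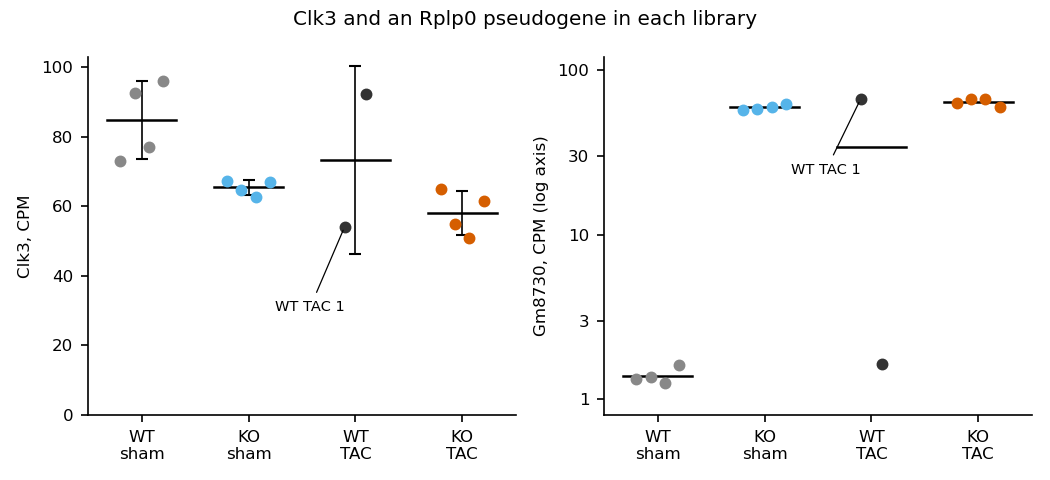
Each point is 1 library, and the bar is the group mean (error bars on the left, SD; none are drawn on the right). The left axis is Clk3 in CPM and the right, logarithmic axis is the Rplp0 pseudogene Gm8730 in CPM; the library labelled wild-type TAC 1 lies with the knockout libraries in both, at 54.2 and 66.8 CPM.

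TAC raised the genes of cardiac load and of the fibrillar matrix in wild-type hearts. Nppa (ENSMUSG00000041616.9), which encodes atrial natriuretic peptide, rose 11.4-fold to 1860 CPM ± 73.8 (SD, n = 2) from 163 ± 51.2 (n = 4). Myh7, the fetal beta-myosin heavy chain, rose 13.7-fold to 5210 ± 744 from 380 ± 211. Nppb (B-type natriuretic peptide) rose 3.39-fold, Acta1 (skeletal alpha-actin) 5.44-fold and Ankrd1, a stress-responsive titin-associated protein, 3.22-fold. Of 28 load-induced genes tested, 24 rose and 4 did not pass (26 rose adjusted over the list alone; camera adjusted p = 1.08e-21, and adjusted p = 0.0718 with an estimated correlation). Meox1, a transcription factor of activated fibroblasts counted in this list, rose 3.86-fold. Of 48 fibrillar matrix and fibrosis genes, 44 rose, 1 fell and 3 did not pass (45 and 1 adjusted over the list alone; camera adjusted p = 2.94e-40, and adjusted p = 0.0127 with an estimated correlation). Among them Ltbp2, a latent TGF-beta binding protein, rose 14.9-fold to 80.4 ± 1.57 CPM, Postn (periostin, made by activated fibroblasts) 10.1-fold to 683 ± 278 CPM, and Cilp, a matricellular protein, 16.1-fold to 286 ± 72.3 CPM.

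Other large rises were those of the collagen-binding proteoglycan Fmod (23.1-fold, to 35.7 ± 15.4 CPM) and Thbs4, a thrombospondin (21-fold, to 142 ± 60.1 CPM). Sprr1a reached 4.81 ± 1.67 CPM from 0.105, Cilp2 5.28 ± 6.05 from 0.253, and Serpinb1c, whose close relatives could share its reads, 10.3 ± 6.33 from 0.269. C1qtnf3 and the growth factor Ereg reached 1.57 ± 0.814 and 1.21 ± 0.35 CPM from 0.0195 and 0.0137 CPM. Tnmd reached 1.88 ± 0.0598 from 0.111 CPM. The sham counts of these 6 genes are too few for a fold. The fibroblast markers rose in 9 of 18 and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 8.34e-06, and 0.201 as the adjusted p with an estimated correlation). Mfap5 rose 4.33-fold, Col1a1 3-fold and Col1a2 2.76-fold (the chains of type I collagen), while Scara5 fell by 1.68 on the log2 scale. Basement membrane genes rose in 6 of 16 (7 up and 1 down adjusted over the list alone; camera adjusted p = 0.00327, and adjusted p = 0.497 with an estimated correlation). Examples were Col4a1 at 2.04-fold and Col4a2 at 1.84-fold, the chains of type IV collagen. Macrophage and monocyte markers rose in 9 of 23 (13 adjusted over the list alone; camera adjusted p = 7.71e-05, and adjusted p = 0.422 with an estimated correlation). Examples were Fcgr1 at 2.44-fold, the chemokine receptor Cx3cr1 at 2.42-fold, Ly86 at 1.83-fold and the complement gene C1qb at 1.56-fold.

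Some genes of the adult myocyte and of fat use fell in wild-type TAC hearts. Of 24 calcium and potassium handling genes, 10 fell, 1 rose and 13 did not pass (11 and 1 adjusted over the list alone; camera adjusted p = 0.000203, and adjusted p = 0.201 with an estimated correlation). The potassium channel genes Kcnv2, Kcnj3, Kcnd2 and Kcnd3 fell by 2.11, 1.34, 0.82 and 0.77 on the log2 scale. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at 6239 ± 234 against 7448 ± 313 CPM (log2 −0.26, adjusted p = 0.05, not past the threshold). Myh6, the adult alpha-myosin heavy chain, was at 11520 ± 2799 against 14110 ± 1683 CPM (adjusted p = 0.227). Of 34 fatty acid oxidation genes, 15 fell and none rose (24 fell adjusted over the list alone; camera adjusted p = 1.93e-10, and adjusted p = 0.298 with an estimated correlation). The mean log2 CPM of this list was 8.08 to 8.245 in wild-type sham. It was 7.523 in the library labelled wild-type TAC 1 and 7.913 in wild-type TAC 2, so the fall was smaller in the latter. Acaa2 and Hadh, enzymes of beta-oxidation, fell by 0.68 and 0.50, and the carnitine carrier Slc25a20 by 0.45. Acot1, which has near-identical relatives, fell by 2.1. Of 20 tricarboxylic acid cycle genes, 3 fell (6 adjusted over the list alone; camera adjusted p = 0.002, and adjusted p = 0.422 with an estimated correlation). Among the largest falls were those of Aox3, Rp1, the water channel gene Aqp4 (−3.23, from 7.66 ± 4.71 to 0.797 ± 0.393 CPM), Ankrd63, the chemokine gene Ccl11 (−3.11), Cfap61 and Uckl1os. The last is an antisense transcript that cannot be told from its partner without the strand setting.

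Smaller groups moved as well. Sarcomere genes rose in 6 of 24 (9 adjusted over the list alone; camera adjusted p = 0.00208, and adjusted p = 0.535 with an estimated correlation), among them the intermediate filament gene Des at 1.6-fold. Heat shock genes rose in 6 of 17 (9 adjusted over the list alone; adjusted p = 0.00116, and adjusted p = 0.422 with an estimated correlation). Examples were Hspb1 at 1.67-fold and Hspb7 at 1.42-fold. Interferon response genes rose in 3 of 23 (6 adjusted over the list alone; adjusted p = 3.16e-05, and adjusted p = 0.422 with an estimated correlation). Examples were Mx1 and Ifit1. Cytokine and chemokine genes rose in 6 of 24 (7 up and 1 down adjusted over the list alone; adjusted p = 0.0275, and adjusted p = 0.422 with an estimated correlation). Lgals3 and Cxcl10 were among them. Cell cycle genes rose in 9 of 34 and fell in 1 (23 and 1 adjusted over the list alone; adjusted p = 1.66e-08, and adjusted p = 0.371 with an estimated correlation). Cdk1, Ect2 and Anln were higher and the kinetochore gene Cenpf was lower (−2.17). Clock output genes fell in 7 of 18 and rose in 1 (9 and 3 adjusted over the list alone; adjusted p = 0.0109, and adjusted p = 0.298 with an estimated correlation). Hlf, Per3, Tef and Cry2 were lower. Arntl, a core clock gene, was 18.2 and 23.7 CPM in the wild-type TAC libraries against 4.53 to 9.38 in wild-type sham. The labels do not give the time of collection, so a difference in it cannot be told apart from TAC for these genes. Ribosomal protein genes rose in 1 of 47 (1 adjusted over the list alone; adjusted p = 0.00807, and adjusted p = 0.923 with an estimated correlation). The CLK kinases and SR proteins had none of 25 past the threshold (0 adjusted over the list alone; camera lower, adjusted p = 0.0201, and adjusted p = 0.742 with an estimated correlation). Cardiac splicing regulators fell in 2 of 25, Rbfox1 and Rbm20 (2 adjusted over the list alone; adjusted p = 0.0202, and adjusted p = 0.47 with an estimated correlation).

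In all, 1912 of 15651 genes passed in wild type, 1082 higher and 830 lower after TAC (edgeR, adjusted p under 0.05), 579 of them at least 2-fold. The count fell to 512 without the library labelled wild-type TAC 1, which also took the mean of the CLK and SR protein list from −0.15 to 0.03, and to 938 with 10-week libraries alone. With a clock gene score as a covariate it was 612. Of 70 called genes followed individually, 42 passed whichever library was left out and 25 did not pass without that library.

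**Figure D2:**
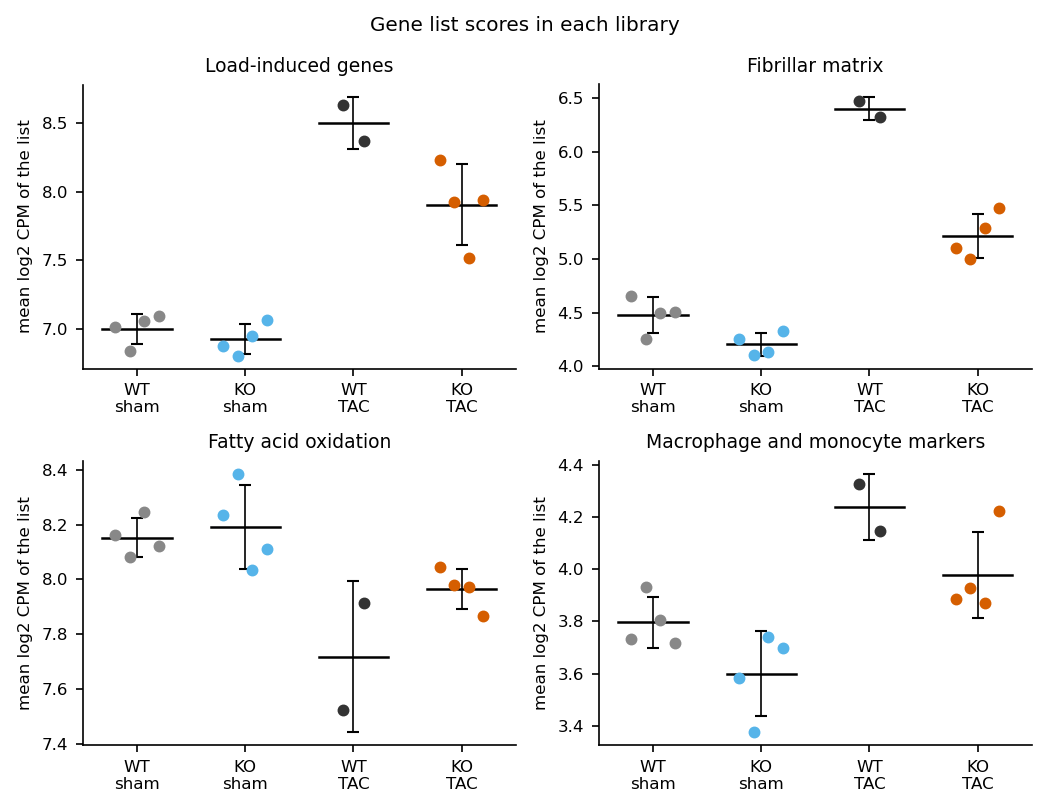
Each point is 1 library, the bar is the group mean and the error bars are SD, and the axis of each panel is the mean log2 CPM over the genes of a list. Both load-induced and fibrillar matrix scores are higher after TAC in both genotypes, and the matrix score is 6.32 and 6.48 in the wild-type TAC libraries against 5 to 5.47 in knockout TAC.

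Knockout hearts also responded to TAC with higher load and matrix genes. Nppa rose 4.75-fold to 844 CPM ± 216 from 178 ± 49.7 (SD, n = 4 and 4), Myh7 4.3-fold to 1917 ± 776 from 446 ± 207, Nppb 2.4-fold, Acta1 4.85-fold and Ankrd1 1.97-fold. Atp2a2 fell by 0.26 (adjusted p = 0.0194), and Myh6 was at 12770 ± 1758 against 13850 ± 786 CPM (adjusted p = 0.543). Load-induced genes rose in 23 of 28 (25 adjusted over the list alone; camera adjusted p = 9e-17, and adjusted p = 0.153 with an estimated correlation). Fibrillar matrix genes rose in 38 of 48 and fell in 1 (45 and 1 adjusted over the list alone; adjusted p = 1.71e-24, and adjusted p = 0.0747 with an estimated correlation). Examples were Ltbp2 at 4.37-fold, Cilp at 4.28-fold and the fibronectin gene Fn1 at 1.89-fold.

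Fmod (8.19-fold), the stress cytokine Gdf15 (5.89-fold, to 8.78 ± 4.22 CPM), Col8a2 (5.61-fold), Comp (4.99-fold) and the protease inhibitor Timp1 (4.76-fold) were among the other largest rises. Sprr1a and Serpinb1c rose from 0.128 and 0.232 CPM to 1.05 and 2.5 CPM, too few counts in sham for a fold. Fibroblast markers rose in 8 of 18 and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.000136, and adjusted p = 0.299 with an estimated correlation). Examples were Mfap5 at 2.3-fold, Col1a1 at 1.9-fold, Pi16 at 1.72-fold and Col1a2 at 1.67-fold. Macrophage and monocyte markers rose in 12 of 23 (15 up and 1 down adjusted over the list alone; adjusted p = 2.02e-05, and adjusted p = 0.413 with an estimated correlation). Examples were Fcgr1 at 2.2-fold and the complement genes C1qb and C1qc at 1.64-fold and 1.49-fold. Cytokine and chemokine genes rose in 7 of 24 (10 up and 1 down adjusted over the list alone; adjusted p = 0.00131, and adjusted p = 0.299 with an estimated correlation). Examples were Lgals3 at 2.72-fold and Ccl8 at 2.65-fold. Endothelial markers rose in 4 of 20 (5 adjusted over the list alone; adjusted p = 0.000142, and adjusted p = 0.413 with an estimated correlation). Examples were Ly6c1 at 1.33-fold and Pecam1, a junction protein of endothelium, at 1.27-fold. Smooth muscle and pericyte markers rose in 3 of 17 and fell in 1 (4 and 2 adjusted over the list alone; adjusted p = 0.0171, and adjusted p = 0.498 with an estimated correlation).

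Calcium and potassium handling genes fell in 9 of 24 (10 adjusted over the list alone; adjusted p = 0.000238, and adjusted p = 0.234 with an estimated correlation). The channel genes Kcnv2, Kcnj3, Kcnd2 and Cacna1c changed by −1.05, −0.83, −0.75 and −0.45 (log2). Fatty acid oxidation genes fell in 8 of 34 (13 adjusted over the list alone; adjusted p = 2.02e-05, and adjusted p = 0.426 with an estimated correlation). Examples were Decr1, Etfdh and Acaa2 at −0.35, −0.31 and −0.37. CLK kinases and SR proteins fell in 6 of 25 (8 adjusted over the list alone; adjusted p = 0.0036, and adjusted p = 0.568 with an estimated correlation). Srsf5 changed by −0.42, Son by −0.39, the kinase gene Prpf4b by −0.30 and Srsf1 by −0.26. The share of reads outside annotated features was lower by 4.64 percentage points after TAC (−4.64), without overlap between the groups. A link of these genes to that share therefore cannot be told apart from TAC. Cardiac splicing regulators fell in 2 of 25 (6 adjusted over the list alone; adjusted p = 0.0201, and adjusted p = 0.466 with an estimated correlation), Rbfox1 by 1.38-fold and Rbm20 by 1.27-fold. Clock output genes fell in 5 of 18 (7 adjusted over the list alone; adjusted p = 0.0476, and adjusted p = 0.413 with an estimated correlation). Per3, Hlf, Tef and Nr1d2 were lower. In these groups knockout sham 4 and knockout TAC 3 stood apart. Arntl was 24.3 CPM in knockout sham 4 against 4.41 to 5.50 in the other 3. It was 9.02 CPM in knockout TAC 3 against 22.1 to 23.2. Here too the time of collection is not known, so the falls of clock output genes cannot be assigned to TAC alone. Among the largest falls were those of Pfkfb1 (4.99-fold), which makes a regulator of glycolysis, Ccl11 (4.96-fold), Fgf10, Tll2, Gpr75, Rp1 and Xlr4b, a member of a family of near-identical copies.

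Interferon response genes rose in 5 of 23 (11 adjusted over the list alone; adjusted p = 2.9e-05, and adjusted p = 0.426 with an estimated correlation). Examples were Rsad2, Irf7 and Bst2. Heat shock genes rose in 7 of 17 (8 adjusted over the list alone; adjusted p = 0.000238, and adjusted p = 0.413 with an estimated correlation). Hspb1 was among them. Immediate early genes rose in 4 of 24 (9 adjusted over the list alone; adjusted p = 0.000125, and adjusted p = 0.466 with an estimated correlation). Cell cycle genes rose in 1 of 34, Aurka, and fell in 1, Cenpf (the same counts adjusted over the list alone; adjusted p = 0.000238, and adjusted p = 0.466 with an estimated correlation). Ribosomal protein genes rose in 2 of 47 (2 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.666 with an estimated correlation). Basement membrane genes rose in 3 of 16 (3 adjusted over the list alone; adjusted p = 0.0432, and adjusted p = 0.589 with an estimated correlation). Lymphocyte markers had 0 of 8 past the threshold (0 adjusted over the list alone; higher, adjusted p = 0.0117, and adjusted p = 0.413 with an estimated correlation) and erythroid markers 1 of 7 (1 adjusted over the list alone; higher, adjusted p = 0.0334, and adjusted p = 0.52 with an estimated correlation).

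In knockout hearts 2033 genes passed, 1053 higher and 980 lower after TAC, 336 of them at least 2-fold (edgeR). The count was 15 with 10-week libraries alone, 588 with age as a factor, 0 with the no-feature share and 275 with a clock gene score as a covariate, and 797, 995, 1036, 1267, 1272 and 1283 without knockout sham 2, knockout sham 1, knockout TAC 4, knockout TAC 2, knockout sham 3 and knockout TAC 1. Of 60 called genes followed individually, 41 passed whichever library was left out.

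In sham hearts the cardiac response genes followed in every comparison did not pass between the genotypes. Nppa was 178 ± 49.7 CPM in knockout against 163 ± 51.2 in wild type (SD, n = 4 and 4, adjusted p = 0.816), and Myh7 446 ± 207 against 380 ± 211 (0.794). Nppb was 238 ± 79.4 against 198 ± 42.0 (0.587) and Acta1 247 ± 52.3 against 422 ± 186 (0.376). Ankrd1 was 1297 ± 184 against 1222 ± 151 (0.729), Myh6 13850 ± 786 against 14110 ± 1683 (0.931) and Atp2a2 8549 ± 310 against 7448 ± 313 CPM (0.132). The largest rises in knockout were those of the germ cell helicase gene Ddx4 (2.69-fold, 1.61 ± 0.442 against 0.593 ± 0.108 CPM), Gm15737 (2.56-fold), the olfactory receptor gene Olfr1034 (2.19-fold) and Armh4 (1.99-fold, 34.4 ± 5.4 against 17.3 ± 0.593 CPM). They were followed by D3Ertd751e (1.76-fold), Fam81a (1.75-fold), Dync2h1, a dynein of cilia (1.67-fold), and Zfp871 (1.65-fold). Among the largest falls were those of the neurotrophin receptor gene Ngfr (0.323 ± 0.150 against 1.17 ± 0.243 CPM), Bin2 (−1.13) and Rnd1 (−0.90). Gpc3 (−0.70), the gap junction gene Gja4 (−0.60), Igfbp6 (−0.60) and the globin gene Cygb (−0.59) were also lower. Within 5 Mb of Clk3, Atm (chromosome 9, 53439149 to 53536740) and Dmxl2 (54365158 to 54501626) were 1.49-fold and 1.32-fold higher and Islr (58156268 to 58204306) was lower by a log2 change of −0.48.

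Whole lists shifted by small amounts in sham hearts. The fibrillar matrix list was lower in knockout (mean log2 −0.29), with 0 of 48 past the threshold and 11 lower adjusted over the list alone (camera adjusted p = 2.35e-06, and adjusted p = 0.471 with an estimated correlation). Markers of endothelium, fibroblasts, smooth muscle and pericytes, and macrophages were lower by means of −0.26, −0.27, −0.35 and −0.20, with no member past the threshold over all genes (5, 6, 5 and 2 lower, and for smooth muscle and pericytes 1 higher, adjusted over the list alone; camera adjusted p = 0.000172, 0.000172, 0.000479 and 0.00081). With an estimated correlation their adjusted p was 0.471, 0.471, 0.471 and 0.532. Among the members, Pecam1 was 205 ± 21.4 against 252 ± 27.9 CPM (adjusted p = 0.133), Col1a1 93.1 ± 16.2 against 135 ± 20 (0.0609), Cd68, a macrophage lysosomal protein, 5.08 ± 0.551 against 7.65 ± 0.741 (0.0598) and C1qc 29.6 ± 4.05 against 38.2 ± 1.74 (0.0695). Angiogenesis, cytokine, cell cycle, basement membrane, lymphocyte and erythroid lists were lower as well, with 0 members past the threshold (0, 0, 0, 0, 1 and 2 lower adjusted over the list alone; camera adjusted p = 0.000479, 0.00279, 0.00608, 0.0242, 0.0315 and 0.0107, and adjusted p = 0.471, 0.471, 0.651, 0.651, 0.471 and 0.532 with an estimated correlation). Mitochondrially encoded transcripts were higher by a mean of 0.26, with 0 of 11 past the threshold (0 adjusted over the list alone; adjusted p = 0.000778, and adjusted p = 0.532 with an estimated correlation). All 11 were positive in log2, but they differ widely in level and each weighs the same in the mean of this list. In wild-type sham mt-Atp6 and mt-Co2 were at 2.71 ± 0.909 and 3.84 ± 0.891 CPM, against 9289 ± 1754 for mt-Co1. Over libraries, the percent of counts from mitochondrial genes was 5.64 ± 0.0938 in knockout sham against 4.82 ± 0.907 in wild-type sham (exact two-sided permutation, p = 0.143, n = 4 and 4). Nuclear-encoded oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation and calcium and potassium handling genes were also higher, none with a member past the threshold (0 adjusted over the list alone; adjusted p = 0.0117, 0.0164, 0.0242 and 0.0242, and adjusted p = 0.82, 0.61, 0.734 and 0.471 with an estimated correlation). The share of reads outside annotated features was 2.16 percentage points higher in knockout sham (exact two-sided permutation, p = 0.0857, n = 4 and 4).

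Rplp0 was the ribosomal protein gene that passed, at 381 ± 7.43 against 501 ± 48.1 CPM (−0.40, adjusted p = 0.0333). In the knockout libraries 3 of its pseudogenes were counted far higher, so the counts of Rplp0 and of these near-identical copies cannot be read separately. The CLK kinases and SR proteins did not differ as a list (0 of 25 past the threshold, 0 adjusted over the list alone, adjusted p = 0.487). The closest relative in that list by p, Clk1, was 237 ± 23.5 against 169 ± 22.8 CPM (adjusted p = 0.104). In sham hearts 139 genes passed (edgeR), 90 higher and 49 lower in knockout, a split of 86 and 72 with upper-quartile factors, with 2817 at an unadjusted p under 0.05. The count was 0 with 10-week libraries alone (582 with DESeq2 and 671 with limma-voom on all libraries) and 8, 11, 12, 17, 23, 25 and 65 without wild-type sham 3, knockout sham 2, knockout sham 3, wild-type sham 4, knockout sham 1, wild-type sham 2 and knockout sham 4. It was 531, 221 and 217 without wild-type sham 1, the library labelled wild-type TAC 1 and wild-type TAC 2, and 90 without knockout TAC 2. Of 20 called genes followed individually, 1 passed whichever library was left out.

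After TAC, matrix genes were lower in the knockout hearts than in those labelled wild type. Cilp was 50.1 ± 17.1 CPM in knockout (SD, n = 4) against 286 ± 72.3 in wild type (n = 2), a log2 difference of −2.51 ± 0.25 (SE, adjusted p = 0.000146), with Ltbp2 at 16.7 ± 4.63 against 80.4 ± 1.57 (−2.26) and Thbs4 at 20.3 ± 11.2 against 142 ± 60.1 (−2.79). Col1a1 was 177 ± 27.0 against 404 ± 13.4 CPM (−1.19) and Col1a2 262 ± 38.8 against 578 ± 76.5 (−1.14). Loxl3, a lysyl oxidase that crosslinks collagen, was 10.1 ± 1.43 against 29.6 ± 8.81 (−1.55). Fibrillar matrix genes were lower in 29 of 48 and higher in none (42 lower adjusted over the list alone; camera adjusted p = 1.33e-40, and adjusted p = 0.0123 with an estimated correlation). Fibroblast markers were lower in 7 of 18 and higher in 1 (10 and 1 adjusted over the list alone; adjusted p = 1.71e-08, and adjusted p = 0.142 with an estimated correlation). Serpinf1 and Mfap5 differed by −1.19 and −1.27 (log2). Of the 18 fibroblast markers, 6 are also in another list, so the lists are not independent. Col1a2 is among the matrix genes too, and Mfap5 among the load-induced genes.

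Load-induced genes were lower in 6 of 28 (12 adjusted over the list alone; camera adjusted p = 1.35e-10, and adjusted p = 0.28 with an estimated correlation). Nppa was 844 ± 216 against 1860 ± 73.8 CPM (−1.14, adjusted p = 0.0478) and Ankrd1 2557 ± 319 against 3941 ± 46.0 (−0.62, 0.0342). Meox1 was lower by a log2 change of −1.27, and Fhl1 and Enah, partners of the sarcomere and the actin skeleton, by −1.02 and −0.50. Myh7 (1917 ± 776 against 5210 ± 744 CPM, adjusted p = 0.144), Nppb (571 ± 206 against 670 ± 30.1, 0.789), Acta1 (1201 ± 612 against 2295 ± 1457, 0.434), Myh6 (0.708) and Atp2a2 (0.266) did not pass. Further genes with the largest falls were Fmod (−2.90), Frem1 (−2.69), Col12a1 (−2.45), and Chodl, Tnmd and C1qtnf3, which were at 0.0367, 0.0815 and 0.244 CPM in knockout against 1.95, 1.88 and 1.57 CPM.

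Few channel and metabolic genes passed one by one in knockout TAC hearts, and the means of their lists were higher. Kcnv2 was 12.0 ± 2.61 against 4.69 ± 1.43 CPM (2.53-fold) and Kcnj3 75.8 ± 16 against 43.9 ± 10.1 (1.73-fold). Calcium and potassium handling genes were higher in 2 of 24 (2 adjusted over the list alone; camera adjusted p = 0.00113, and adjusted p = 0.28 with an estimated correlation). Fatty acid oxidation genes were higher in 1 of 34, Ppargc1a, a coactivator of mitochondrial genes, at 350 ± 78.6 against 203 ± 24.8 CPM (17 higher adjusted over the list alone; adjusted p = 8.68e-10, and adjusted p = 0.296 with an estimated correlation). The mean log2 CPM of this list was 7.523 in the library labelled wild-type TAC 1. In wild-type TAC 2 it was 7.913, within the 7.866 to 8.044 of knockout TAC, so the list difference rests mainly on wild-type TAC 1. Tricarboxylic acid cycle genes and nuclear-encoded oxidative phosphorylation genes had no member past the threshold (0 adjusted over the list alone), with all 20 and all 52 positive in log2 (adjusted p = 8.5e-06 and 0.000237, and adjusted p = 0.296 and 0.884 with an estimated correlation). Cell cycle genes, basement membrane genes and macrophage markers were lower, with 0 of 34, 1 of 16 and 0 of 23 past the threshold (0, 2 and 0 adjusted over the list alone; adjusted p = 8.68e-10, 0.000237 and 0.000643, and adjusted p = 0.296, 0.513 and 0.513 with an estimated correlation). The other largest rises were those of A530016L24Rik (2.06-fold), Hsbp1l1 (2.05-fold), Ifi205 (2.01-fold, with near-identical relatives), Ndnf (2-fold) and Ociad2 (1.98-fold). Next came the myosin light chain kinase gene Mylk4 (1.94-fold, 234 ± 41.3 against 121 ± 8.89 CPM) and Dusp18 (1.94-fold). The splicing regulator gene Rbfox1 was 1.64-fold higher. The CLK kinases and SR proteins did not differ as a list (0 of 25, 0 adjusted over the list alone, adjusted p = 0.792). Within 5 Mb of Clk3, Itga11 (62677826 to 62783982), Loxl1 (58287738 to 58313186) and Islr were lower by log2 changes of −1.33, −0.90 and −0.67 and Dmxl2 was 1.31-fold higher.

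After TAC 232 genes passed between genotypes, 59 higher and 173 lower in knockout (edgeR, 82 at least 2-fold). The count was 46 without the library labelled wild-type TAC 1, 359 without wild-type TAC 2, 94, 149 and 152 without knockout TAC 2, 3 and 1, 60 with the groups compared alone and 120 with 10-week libraries alone. Of 34 called genes followed individually, 9 passed whichever library was left out, and 24 did not without the library labelled wild-type TAC 1.

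The TAC effect itself differed between genotypes for 3 genes, each with a smaller rise in knockout. Postn (ENSMUSG00000027750.16, chromosome 3, 54361109 to 54391037) rose from 68.2 ± 16.7 to 683 ± 278 CPM in wild type and from 66.2 ± 6.99 to 182 ± 33.0 in knockout, a difference of −1.87 ± 0.29 (log2, SE). Ddah1 (ENSMUSG00000028194.15, chromosome 3, 145758675 to 145894277), an enzyme that degrades an inhibitor of nitric oxide synthesis, rose from 7.11 ± 0.592 to 19.0 ± 0.473 in wild type and from 7.96 ± 0.783 to 10.3 ± 0.464 in knockout (−1.04 ± 0.15). Ppm1e, a protein phosphatase gene (ENSMUSG00000046442.4, chromosome 11, 87226906 to 87359023), stood at 17.8 ± 1.53 and 48.9 ± 3.63 in wild type and at 28.1 ± 4.70 and 34.9 ± 3.66 CPM in knockout (−1.14 ± 0.17). Its change in knockout did not pass (adjusted p = 0.0756), and in sham hearts it was already 1.57-fold higher in knockout (adjusted p = 0.0203). All 3 had an adjusted p of 0.0403. Loxl3 (−1.28) and the organic cation transporter gene Slc22a4 (−1.18) came next and did not pass (adjusted p = 0.0553 each). Nor did Nppa (−1.26, adjusted p = 0.428), Ankrd1 (−0.71, 0.32), Myh7 (−1.67, 0.629), Nppb (−0.50, 0.877), Acta1 (−0.17, 0.994), Myh6 (0.17, 0.916) or Atp2a2 (0.999), or Clk3 (0.03, 0.996).

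As lists, the matrix genes rose less in knockout (mean −0.87, 1 of 48 past the threshold and 23 lower adjusted over the list alone; camera adjusted p = 8.48e-28, and adjusted p = 0.0488 with an estimated correlation). Over libraries, an exact two-sided permutation of genotype within each surgery gave p = 0.0905 for the mean score of the list, not past 0.05. Load-induced genes (−0.50, 0 of 28, 11 lower adjusted over the list alone), cell cycle genes (−0.34, 0 of 34 and 0), fibroblast markers (−0.27, 0 of 18, 1 higher and 5 lower), sarcomere genes (−0.19, 0 of 24 and 0) and mitochondrially encoded transcripts (−0.17, 0 of 11 and 0) also had lower TAC effects in knockout (camera adjusted p = 4.67e-08, 0.000703, 0.00256, 0.00865 and 0.0291). Fatty acid oxidation genes (0.16, 0 of 34 and 0), tricarboxylic acid cycle genes (0.08, 0 of 20 and 0), endothelial markers (0.21, 0 of 20 and 0) and smooth muscle and pericyte markers (0.36, 0 of 17 and 0) had higher ones (adjusted p = 5.25e-05, 0.0344, 0.00133 and 0.00643). Each of these 9 lists other than the matrix list had an adjusted p of 0.778 with an estimated correlation. Without the library labelled wild-type TAC 1 the means were −0.77 for the matrix list, 0.005 for fatty acid oxidation, 0.06 for mitochondrially encoded transcripts, −0.15 for the cell cycle, −0.15 for fibroblast markers and 0.08 for the tricarboxylic acid cycle. All of these but the matrix list were no longer called. The interaction called 3 genes with edgeR, all lower (1022 at an unadjusted p under 0.05), 37 with DESeq2, 7 with limma-voom and 66 with no filter. It called 0 with age as a factor, 1 without the library labelled wild-type TAC 1 and 32 without wild-type TAC 2, and leaving out 8 of the other 12 libraries in turn also gave 0. It called 1 without wild-type sham 1 or knockout sham 4 and 7 without knockout TAC 3. None of the 3 genes passed whichever library was left out, and without the library labelled wild-type TAC 1 none of them passed.

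Across the 15651 genes the TAC effects of the genotypes correlated with Pearson's r = 0.671 and Spearman's rho = 0.649. Genes are not independent replicates, and the comparisons share no libraries. Of the genes called, 965 passed in both genotypes, all in the same direction. These were 544 higher and 421 lower, against 72.8 and 52 for independent lists. The effect was larger in wild type for 84% of the 965. The correlation was 0.517 without the library labelled wild-type TAC 1, 0.598 without wild-type TAC 2 and 0.499 with 10-week libraries alone.

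**Figure D3:**
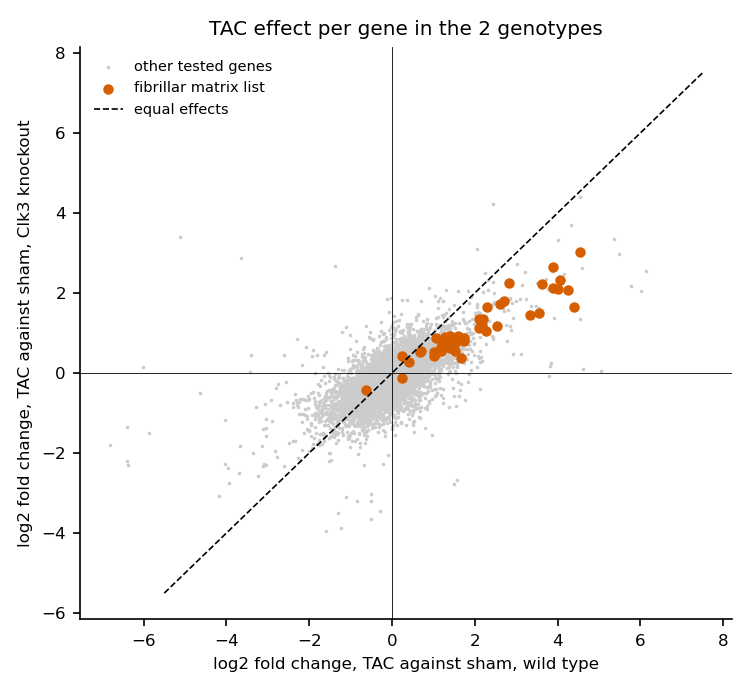
Each point is a tested gene, with its log2 fold change of TAC against sham in wild type on the horizontal axis and in knockout on the vertical axis; orange points are the 48 fibrillar matrix genes and the dashed line marks equal effects. Most matrix genes lie to the right of 0 and below the line, with means of 1.97 in wild type and 1.10 in knockout.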

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

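Tests chosen only after the result was seen were those of Rplp0 reads, of a single wild-type TAC library, of a uniformly smaller response and of the share of non-myocyte cells; the wording of the sham pattern was also changed after its tests were first run. The other tests were fixed before their results were seen.

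The first pattern is the high count of 3 Rplp0 pseudogenes in the 8 knockout libraries and in the library labelled wild-type TAC 1. Gm8730, Gm14165 and Gm9625 are processed pseudogenes on chromosomes 8, 2 and 13, 98.7%, 97.2% and 97.4% identical to Rplp0. Between wild-type and knockout sham hearts Rplp0 dropped by 120 CPM while the 3 rose by 81.0 CPM in sum, a ratio of 1.48, so reads assigned to the pseudogenes, as a sequence variant in Rplp0 would cause, remain a candidate explanation. Whether the label of wild-type TAC 1 is wrong cannot be told apart from a carried variant: of 52 genes that part the knockout libraries from wild-type sham, it lay nearer the knockout mean in 69.2% and wild-type TAC 2 in 65.4%. The knockout libraries included TAC and the wild-type ones did not, so genes moved by TAC can be among the 52. Xirp2 was 1440 CPM in wild-type sham, 2500 in knockout, and 7850 and 3620 in wild-type TAC 1 and 2. Surgery can therefore raise both shares, which do not decide the label. The lowest share of a knockout library, left out of its own mean, was 76.9%, but the genes were chosen with the knockout libraries, so this share sets no fair bound. The genotype named by the label stays open as well, untested, because no strain variant data were used here.

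The second pattern is the smaller rise of fibrillar matrix genes after TAC in knockout hearts, a mean log2 difference of −0.87 between the TAC effects. A single library as the whole cause is argued against: without the library labelled wild-type TAC 1 the mean was −0.767 and without wild-type TAC 2 it was −0.914. The leave-one-out ranges of the matrix list and the macrophage markers did not overlap, which goes against a response smaller by the same factor in every list. Such ranges show the pull of single libraries and not sampling error, so they do not exclude it. The ratio of the knockout to the wild-type effect was 0.558 for the matrix list (0.510 to 0.594 over leave-one-out fits) and 0.879 for macrophage markers (at least 0.669). It was 0.818 for interferon (at least 0.626), 1.22 for heat shock (at least 0.734) and 1.33 for cytokine genes (at least 0.898). The other 6 lists that rose in wild type overlap the matrix range: load-induced genes at 0.673 (0.593 to 0.748), fibroblast markers at 0.621 (0.544 to 0.745), basement membrane at 0.623 (0.476 to 0.904), sarcomere at 0.547 (0.345 to 0.684), cell cycle at 0.496 (0.221 to 0.690) and ribosomal proteins at 0.887 (0.451 to 3.2). For these a shared smaller response stays open, and for the lists above the matrix range it is not excluded. Of the fibroblast markers, 6 of 18 are also in another list, so these ratios are not independent. A smaller effect was not particular to the matrix list. Of the 965 genes called in both genotypes, 84% had the larger effect in wild type. Calls in wild type rest on 2 TAC libraries and take larger effects, which can raise this share. Chance assignment of genotype within each surgery is not excluded, with an exact two-sided permutation p of 0.0905 over all reassignments of the matrix score. An effect of genotype and a difference in the severity of the load between animals therefore stay open. Whether a wrong label for wild-type TAC 1 has a part in the smaller rise was not tested. Leaving that library out gave −0.767 and left 1 library of wild-type TAC. No fit placed that library in the knockout group. Its matrix score of 6.476 lay above the 5 to 5.471 of the knockout TAC libraries and the 6.325 of wild-type TAC 2. This score does not decide the label, and a wrong label stays open. Were the label wrong, the highest matrix score would belong to a knockout heart. The smaller rise would then rest on 1 wild-type TAC library.

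The third pattern is the genotype difference in sham hearts. The 4 against 4 split by genotype called 139 genes, and the highest of the other splits called 12. Thus 1 of 35 splits, the labelled one, gave as many. That is the smallest share this test can give, so it argues against chance and does not exclude it. A bias that follows the share of reads in no feature cannot be told apart from genotype: the slope on that share within the sham groups correlated with the genotype difference at r = 0.157 across genes, against −0.0621 for the slope within the TAC groups. With the share as a covariate 122 genes passed, 46 of them among the 139. The median exon length was 10162 bases in the genes higher in knockout, 3146 in those lower and 4114 in all tested. Length runs against what this bias needs, with a rank correlation of 0.107 with the genotype difference and −0.142 with the slope on the share, but the mean share was 2.16 percentage points higher in knockout sham, which keeps the bias open. A lower share of non-myocyte cells may also account for the list shifts, since the means of the endothelial, fibroblast, macrophage and pericyte lists were −0.256, −0.273, −0.199 and −0.345, the highest being −0.199. Of the most abundant members, Gsn moved about as its list (−0.26, 1139 ± 115 against 1366 ± 159 CPM, SD, n = 4 and 4). Fabp4 (661 ± 24.1 against 668 ± 34.3), Lyz2 (137 ± 20.5 against 142 ± 11.8) and Des (1543 ± 47.0 against 1576 ± 126) moved less than theirs. In the same order of lists, 3 of 20, 6 of 18, 0 of 23 and 1 of 17 members are also in another list.

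For TAC in knockout hearts, the labelled split called 2033 genes and 1 of 35 splits, the labelled one, gave as many. As in sham hearts, this argues against chance and does not exclude it. The highest other split called 403 and exchanged knockout sham 4 and knockout TAC 3, the libraries apart from their groups in clock genes and also in other genes.

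Of 570 sets of 4 values, 45 were marked for a single library apart from the other 3 of its group (7.89%, against about 5% by chance). In 1 of these, Tnmd in knockout sham, all 4 values (−2.92) are equal at the floor, so no library stands apart. In knockout sham 4, log2 CPM was higher for Arntl (4.61), Eng (7.83), Gdf15 (1.17), Pecam1 (7.88), Rplp0 (8.61) and C1qtnf3 (−1.85, near the floor), and lower for Dbp (5.79), Per3 (5.47) and Tef (7.70); mean log2 CPM was lower for tricarboxylic acid cycle (9.75) and clock output (5.39) lists and higher for ribosomal proteins (7.55). In knockout TAC 3 Acta1 (8.21), Arntl (3.19), Col4a1 (9.35) and the angiogenesis list (5.56) were lower, and Col8a2 (2.81), Igfbp6 (4.47) and Tnmd (−1.13) were higher. In wild-type sham 1 C1qtnf3 (−2.25), Chodl (−0.261), Cilp2 (−0.261), Col8a2 (1.06), the cytokine list (2.41) and the adipocyte list (3.43) were higher and the angiogenesis list (5.75) lower. In knockout TAC 4 Atp2a2 (12.7) and the unfolded protein list (5.22) were lower and Gja4 (3.96), the cytokine list (2.70) and the macrophage list (4.23) were higher. In knockout sham 2 Cilp (3.28) and Rnd1 (0.799) were lower, and Kcnd2 (6.20) was higher. In wild-type sham 4 Col1a2 (7.83) and Hspb1 (7.39) were higher and Kcnj3 (6.58) lower. Knockout sham 3 was lower for A530016L24Rik (4.77) and Kcnv2 (3.95), and wild-type sham 2 for Hsbp1l1 (1.48). Higher single values were those of Cfap61 in knockout TAC 2 (0.432), Ereg in wild-type sham 3 (−2.42), Gpr75 in knockout sham 1 (1.56) and Prpf4b in knockout TAC 1 (7.16).

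A difference between the TAC effects of the genotypes marked 3 genes, Ddah1 (−1.04), Ppm1e (−1.14) and Postn (−1.87). By camera with its preset correlation it also marked the lists of load-induced genes (−0.497), fibrillar matrix (−0.87), fatty acid oxidation (0.161), mitochondrially encoded transcripts (−0.174), the tricarboxylic acid cycle (0.0766), the sarcomere (−0.188), the cell cycle (−0.34), endothelial markers (0.214), fibroblast markers (−0.271) and smooth muscle and pericyte markers (0.363). With an estimated correlation only the matrix list stayed past the threshold (adjusted p = 0.0488, against 0.778 for each of the others).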

How the results depend on the processing

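Alternatives chosen after seeing the data were the no-feature covariate, the clock covariate, coding-sequence counts and leaving out knockout sham 4 and knockout TAC 3. Over all alternatives, 5549 of 6619 values of named genes kept their side of the threshold, 983 lost the call, 83 gained one and 4 reversed. For lists these were 3468 of 3795, 226, 89 and 12. A reversal was counted only where the value was called in the main fit or in the alternative. Values called in neither count as kept even where their sign changed, so not all sign changes are among the reversals. The cause was not tested unless the alternative itself, by fewer libraries, genes or a stricter limit, shows it. RLE factors moved no count by over 1.5 times. No paired analysis was possible because the labels give no replicate numbers.

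The count for TAC in wild type (1912) was 928 with limma-voom, 1158 with age as a factor, 938 with 10-week libraries, 1074 with only its groups, 860 at adjusted p under 0.01, 579 at 2-fold, 595 with the no-feature covariate, 612 with the clock covariate and 1169 with coding counts. For TAC in knockout (2033) these were 4128, 588, 15, within 1.5 times, 549, 336, 0, 275 and 1005. The no-feature share does not overlap between knockout sham (17.1 to 19.0%) and knockout TAC (12.3 to 14.3%), so that covariate takes up the surgery itself. For genotype in sham hearts (139) the count was 582 with DESeq2, 671 with limma-voom, 387 with no filter, 220 with the strict filter, 0 with 10-week libraries, 5 at adjusted p under 0.01, 11 at 2-fold, 297 with the clock covariate and 92 with coding counts. For genotype after TAC (232) it was 467 with DESeq2, 139 with limma-voom, 525 with no filter, 120 with 10-week libraries, 60 with only its groups, 64 at adjusted p under 0.01, 82 at 2-fold, 145 with coding counts and 149 without the pair of other clock phase. For the interaction (3) it was 37 with DESeq2, 7 with limma-voom, 66 with no filter, 0 with age, 10-week libraries, adjusted p under 0.01 or coding counts, 8 with the no-feature covariate, 1 with the clock covariate and 1 without that pair. Leaving out 1 library gave 512 to 2224, 797 to 2306, 8 to 531, 46 to 359 and 0 to 32 in the same order. Where wild-type TAC kept 1 library, that library was assumed to vary like the other groups. The correlation of TAC effects (0.671) was 0.783 at 10 CPM or more, 0.823 among called genes, 0.499 with 10-week libraries and 0.517 to 0.691 without 1 library. Clk3 in sham hearts passed with no filter (−0.40, adjusted p = 0.0378, against 0.0616 to 0.469 under the other alternatives), with −0.44 to −0.32 without 1 library; after TAC it was −0.67 to 0.09.

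With the no-feature covariate Srsf1 (0.0212), Prpf4b (0.0144), Srsf5 (0.00559) and Son (0.169) reversed after TAC in knockout, as did the CLK and SR protein list (0.0335 for TAC in wild type, 0.13 for TAC in knockout, −0.112 for genotype in sham hearts), oxidative phosphorylation (0.107) and splicing regulators (0.0174) after TAC in knockout and fatty acid oxidation in sham hearts (−0.0792). The endothelial list reversed with the clock covariate after TAC in wild type (−0.12). Without wild-type TAC 1 the CLK and SR protein list reversed for TAC in wild type (0.0346, range without 1 library −0.378 to 0.0346) and genotype after TAC (−0.181, range −0.181 to 0.232), and the unfolded protein list for the interaction (−0.308, range −0.308 to 0.254). Without wild-type TAC 2 the unfolded protein list reversed for genotype after TAC (0.198, range −0.364 to 0.198) and the CLK and SR protein list for the interaction (0.2, range −0.213 to 0.2). At 11385818 to 20369637 counts per library, the 36261 genes below the filter were not tested. In simulated counts 14.9% of 1.5-fold differences between TAC effects were recovered, among genes with a mean of at least 1 CPM.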

Other observations

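Several lists had members past the threshold without a call for the list as a whole. Of 24 unfolded protein and integrated stress response genes, 6 rose and 1 fell after TAC in wild type (7 and 3 adjusted over the list alone, camera adjusted p = 0.488). The mean log2 CPM of this list was 5.1 in the library labelled wild-type TAC 1, within the 5.086 to 5.253 of wild-type sham. In wild-type TAC 2 it was 5.658. Mthfd2, an enzyme of mitochondrial folate metabolism, was 20.8 ± 19.8 CPM (SD, n = 2) against 3.05 ± 0.447 (n = 4), Phgdh, the first enzyme of serine synthesis, rose 2.54-fold, and Herpud1, of protein degradation at the endoplasmic reticulum, fell by 0.79 on the log2 scale. In knockout 3 of these rose (4 up and 1 down adjusted over the list alone, adjusted p = 0.0577). Of 22 glycolysis genes, 4 fell and 2 rose in wild type (5 and 3 adjusted over the list alone, adjusted p = 0.929) and 1 fell and 4 rose in knockout (1 and 5 adjusted over the list alone, adjusted p = 0.358). Pfkfb1, Hk2 (hexokinase 2) and Slc2a4, the insulin-responsive glucose transporter, fell by 2.60, 0.37 and 0.40 in wild type, and Pfkp, a phosphofructokinase, rose 1.8-fold; the median of the list was 0.11 and its mean −0.08. Of 24 immediate early genes, 4 rose in wild type, among them Egr2 (4.12-fold) and Myc (2.37-fold) (4 adjusted over the list alone, adjusted p = 0.137).

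Atrial markers rose in 4 of 10 and fell in 3 after TAC in wild type (5 and 3 adjusted over the list alone, camera adjusted p = 0.109) and rose in 4 and fell in 1 in knockout (4 and 2 adjusted over the list alone, adjusted p = 0.148). Schwann cell and neuronal markers rose in 2 of 11 and fell in 1 in wild type (2 and 1 adjusted over the list alone, adjusted p = 0.649), and epicardial markers rose in 1 of 5 (1 adjusted over the list alone, adjusted p = 0.819). Endothelial, smooth muscle and pericyte, angiogenesis, lymphocyte, neutrophil and mast cell, adipocyte and erythroid lists, oxidative phosphorylation, mitochondrially encoded transcripts and the skeletal muscle and lung list were not called after TAC in wild type (adjusted p = 0.66, 0.819, 0.795, 0.271, 0.929, 0.795, 0.137, 0.0759, 0.795 and 0.795). Median and mean differed in sign there for the mitochondrially encoded (0.12 and −0.02), neutrophil and mast cell (0.16 and −0.04), epicardial (−0.18 and 0.29) and skeletal muscle and lung (0.01 and −0.58) lists. Of the 11 mitochondrially encoded members 9 were positive. The falls of mt-Atp6 (−0.97) and mt-Co2 (−0.39) were those of genes at 1.36 and 2.91 CPM in wild-type TAC.

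Pseudogenes Gm6166 and Gm7993 took on separate levels within groups. Gm6166 was 0.0543 to 0.234 CPM in 6 libraries and 5.02 to 10.0 CPM in the other 8, and Gm7993 was 0.0 to 0.338 CPM in 6 and 3.85 to 10.9 CPM in the other 8. These genes were chosen after their values were seen.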
